A study of Mus musculus with 4 samples.

How the data were processed

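Gastric mucosa of the corpus was taken from mice of 2 genotypes, Muc6 +/+ (wild type, 2 libraries) and Muc6 -/- (knockout, 2 libraries), as the sample labels give them. Per the labels' protocols, RNA was extracted with a column kit and libraries were made with a stranded mRNA kit that selects polyadenylated RNA. Per the submitters' processing notes, the genome build was mm10. The aligner, the counting program and the gene annotation are not given in the sources used here, and neither is whether the counting used strand.

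The deposited table holds estimated counts per gene for the 4 libraries, and no normalization had been applied to it as far as the values show. Of the nonzero values, 35.0% were not whole numbers, so the expected counts in the deposited table were rounded to whole numbers before any test. Such estimates share a read among the genes it fits, which makes values of near-identical copies (paralogs, processed pseudogenes and nuclear copies of mitochondrial genes) uncertain, as are values of overlapping genes. Every count column was used, and no row lacked a gene. Of the 34866 rows, 34582 matched a gene of GENCODE release M21 (the same assembly) by identifier without its version, and symbols and positions come from that match. The other 284 rows kept their identifiers. Protein-coding genes made up 21782 rows and pseudogenes 12298. Only 20 rows were long intergenic, antisense, small nucleolar or microRNA genes, and Xist was not analysed here. Of 52 rows that shared a symbol with another row, the row with the most counts kept the plain symbol.

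Total counts were 27946423 and 20895793 in the wild-type libraries and 20327745 and 21717123 in the knockout libraries. Ratios of summed counts carry exact 95% intervals (Clopper-Pearson, conditional on the sum). A gene at 0 in both libraries of a genotype was set against a floor of 3 counts over that group. These intervals and floors cover counting error only. Libraries of a genotype were not duplicates of each other: over genes with at least 10 counts in the pair, the chi-square of their counts was 139 per degree of freedom between the wild-type libraries and 272 between the knockout libraries.

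The comparison of knockout with wild type used edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and test, robust dispersion, TMM factors, filterByExpr with its minimum of 10 counts, no covariate) on 14067 genes, with Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F statistic. CPM values use library sizes multiplied by TMM factors. DESeq2 1.42.0 and limma 3.58.1 (voom) served as alternatives. With 2 libraries against 2, an exact permutation test of a single gene cannot give a p-value below 0.33, so single genes were tested only in models fitted across all genes.

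Gene lists were tested with limma's camera on log2 CPM (prior count of 2) with a preset inter-gene correlation of 0.01. Fixed beforehand were 48 lists of gastric cell types, other tissues, immune and stromal cells, pathways and technical signs, of which 47 had at least 4 tested members. The list of T and NK cells had 3 tested members and was not tested. The number of members past the gene test is also given adjusted over the list alone. Medians and means of lists are of differences in log2 CPM. The alternatives were camera with the correlation estimated per list, fry, and lists without members shared with another list.

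The groups, the test, the gene lists, the alternatives and the rule for named genes were chosen before the data were examined. Named genes were Muc6, the 10 genes with the smallest p in each direction, because fewer than 10 passed the adjusted threshold, among genes with a mean of at least 10 counts in the higher group, no overlap between groups and a symbol that is not a model name, members of the tissue, stromal, immune and technical lists that bear on limits, and a fixed set of gastric, Golgi, stress and sex-linked genes. The rule also took list members past the adjusted threshold, of which there were none. The other list members, the second Nnt entry and the parents of pseudogenes were chosen after their values were seen. The other alternatives were relative log expression factors, upper-quartile factors, library sizes without the 20 most abundant genes, no filter, a filter of at least 50 counts in 2 libraries, edgeR without robust dispersion, the sample number as a block, and leaving out each library in turn. The edgeR fit with the bias-adjusted deviance (legacy=FALSE) was added after seeing the data.

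The gene test was tested on simulated data with the means, library sizes and dispersions of these libraries. There were 14067 genes and 200 changed genes in each of 5 draws, besides the members of the shifted lists given below. Changed genes were drawn only from those above 5 CPM on average. In the simulation of this comparison edgeR recovered 5.2% of genes changed 2-fold, 63.6% of those changed 4-fold, 86.8% of those changed 8-fold and 95.2% of those changed 16-fold. Of its calls, leaving out members of the shifted lists and calls in the wrong direction, 11.6% fell on unchanged genes. DESeq2 recovered 27.6%, 88.4%, 96.4% and 98.4% of them, and 36.2% of its calls, counted in the same way, fell on unchanged genes. On the real libraries edgeR called 0 genes, although Muc6 was 1538-fold lower in knockout. These shares therefore cannot be read as the power of the real comparison. A list shifted up and a list shifted down by 1 log2 unit were called in all 5 draws, and 0 of 90 unshifted lists were called by camera. Simulated genes were drawn independently of each other and unshifted lists at random. The simulation therefore cannot show how often camera calls unshifted lists whose members vary together.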

Results

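Gene expression in the gastric corpus mucosa was measured by RNA sequencing in mice lacking Muc6, a gel-forming mucin of gastric glands, and in wild-type mice. The study was designed to ask how loss of Muc6 relates to gastric carcinogenesis. There were 2 libraries per genotype, with total counts of 27946423 and 20895793 in wild type 1 and 2 and of 20327745 and 21717123 in knockout 1 and 2. The labels do not state that the libraries of a genotype came from separate animals. The p-values of single genes thus measure the spread between these samples, which may be technical. Camera p-values of lists compare the members with the other genes tested, at the preset correlation between members. They do not measure how far a list as a whole varies between libraries of a genotype. For the proliferation list the estimated correlation was 0.739 and the adjusted p by fry was 0.172. Mitochondrial genes took 9.39% and 8.73% of the counts in wild type and 5.97% and 5.41% in knockout. The 20 most abundant genes took 32.2% and 38.8% in wild type and 19.7% and 27.9% in knockout.

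Muc6 (ENSMUSG00000048191.15, minus strand of chromosome 7 at 141633456 to 141655319, mm10) had 8542 and 6000 counts in wild type 1 and 2, and 0 and 10 counts in knockout 1 and 2. In CPM these were 345, 313, 0 and 0.413. The summed counts were 1538-fold lower in knockout (95% interval 836 to 3208). In the fit across all genes the log2 fold change was -10.55 ± 0.999 (SE, n = 2 per group), with an adjusted p of 0.178 by edgeR's quasi-likelihood test and 6.0e-06 by DESeq2. The targeted gene thus followed the labels in all 4 libraries. Without knockout 2 the adjusted p by edgeR's quasi-likelihood test was 0.0159.

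The libraries also differed by genotype in sex-linked genes. The 4 Y-linked genes measured, Ddx3y, Uty, Kdm5d and Eif2s3y, summed to 136 and 121 CPM in wild type and to 1.43 and 2.44 CPM in knockout. Ddx3y, an RNA helicase gene on the Y chromosome, had 952 and 737 counts in wild type and 0 and 1 in knockout, 1786-fold lower (95% interval 320 to 70600). Genotype and Y-linked expression thus could not be separated for any gene group that follows. The list of these genes was lower as a set (4 of 4 members lower, 4 passing when adjusted over the list alone, camera adjusted p = 1.4e-07, adjusted p = 0.792 with an estimated correlation).

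Acid-secreting parietal cell genes fell in knockout mucosa. All 16 tested members were lower in knockout in the fit, 15 of them without overlap between the genotypes, with a median log2 difference of -2.40 (camera adjusted p = 2.0e-07, adjusted p = 0.792 with an estimated correlation). Atp4a, the catalytic subunit of the gastric proton pump, was at 10503 and 10456 CPM in wild type and at 353 and 3331 CPM in knockout (log2 fold change -2.51 ± 1.14, SE, n = 2 per group). Its partner Atp4b was at 4300 and 4101 CPM against 149 and 1326 CPM. Slc26a9, a chloride transporter gene, had a log2 fold change of -1.90 ± 0.33. No member passed over all genes tested, and 3 passed when adjusted over the list alone, namely Kcnq1, Slc26a9 and Slc4a2. Atp4a and Atp4b did not. With all libraries the adjusted p by edgeR's quasi-likelihood test was 0.387 for Atp4a and 0.375 for Atp4b. Without knockout 2, Atp4a was at -4.94 and Atp4b at -4.87 on the log2 scale. That fit rests on knockout 1 alone, where antral genes were counted as given below. The median of the list lay 3.54 log2 units below the wild-type mean in knockout 1 and 1.36 units below it in knockout 2.

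Genes of mucous neck cells and of spasmolytic polypeptide-expressing metaplasia (SPEM), a gland lineage that appears when parietal cells are lost, were higher in knockout. Tff2, the spasmolytic polypeptide, was at 1022 and 679 CPM in wild type and at 11709 and 7314 CPM in knockout (log2 fold change 3.48 ± 0.46, SE, n = 2 per group). Gkn3 was at 9.28 and 25.9 CPM against 613 and 731 CPM (5.26 ± 0.65). Cd44, a surface marker of SPEM, was at 6.01 and 11.7 CPM against 109 and 32.3 CPM, and the secreted inhibitor gene Wfdc2 at 5.08 and 2.97 CPM against 31.4 and 20.5 CPM. The chloride channel gene Cftr was at 0.323 and 0.260 CPM in wild type and at 127 and 24.1 CPM in knockout 1 and 2. The SPEM list rose (camera adjusted p = 0.00103, adjusted p = 0.792 with an estimated correlation), with 12 of 16 tested members higher, 10 of them and 1 lower member, Olfm4, passing when adjusted over the list alone, and its median was 2.52 in knockout 1 and 1.21 in knockout 2. The mucous neck list rose too (camera adjusted p = 0.0227, adjusted p = 0.792 with an estimated correlation, 7 of 10 members higher), and 5 higher members and 1 lower member, Fut9, passed when adjusted over the list alone. No member of either list passed over all genes. Without knockout 1, where antral genes were counted as given below, the SPEM mean was 1.47 against 2.14 (camera adjusted p = 0.0182) and the mucous neck mean 1.79 against 1.61 (camera adjusted p = 0.00639). The SPEM list lost its call without the members it shared with other lists, of which Gkn3 and Aqp5 are also in the mucous neck list (mean 1.69 against 2.14, camera adjusted p = 0.0712). The mucous neck list lost its call without knockout 2 (mean 1.33, camera adjusted p = 0.193) and with library sizes that leave out the 20 most abundant genes (mean 1.66, camera adjusted p = 0.0571). A4gnt, which makes the glycan cap of gland mucins, was at 70.3 and 82.8 CPM in wild type and at 56.7 and 283 CPM in knockout.

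**Figure D1:**
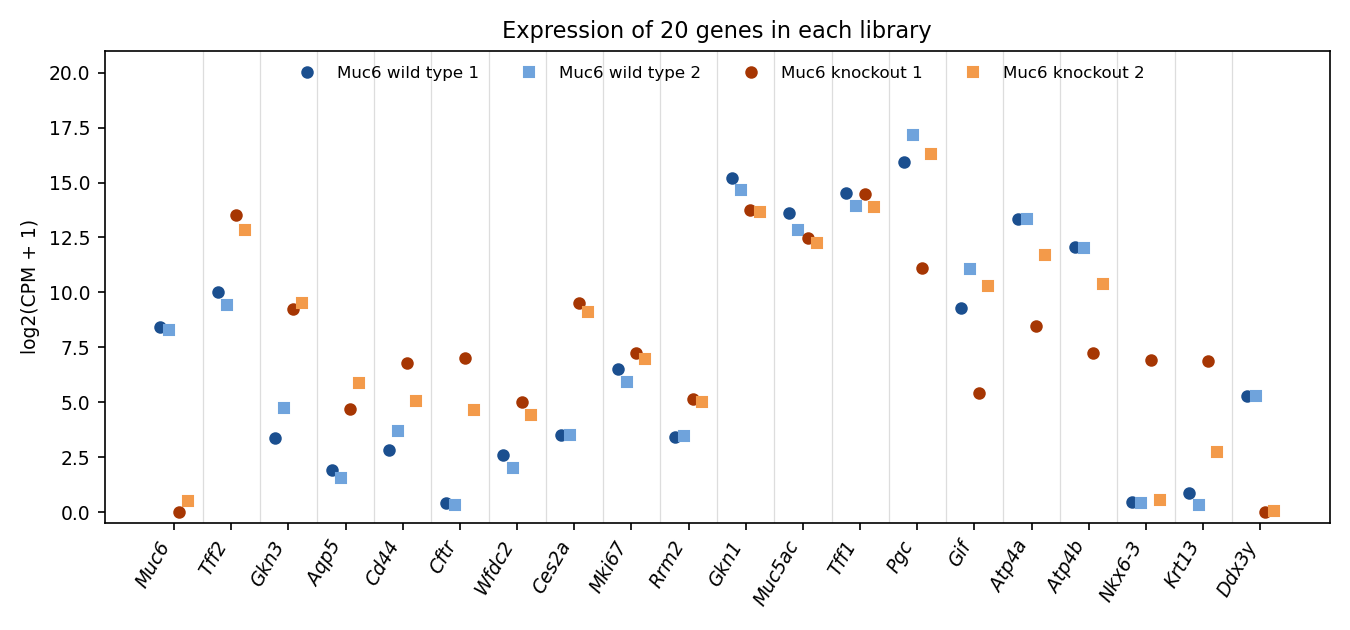
Each point is the expression of a gene in 1 library, as log2(CPM + 1), for 20 genes along the horizontal axis, with circles for replicate 1 and squares for replicate 2 of wild type (blue) and knockout (orange). Muc6 lies at 345 and 313 CPM in wild type and at 0 and 0.413 CPM in knockout, and Pgc lies at 2238 CPM in knockout 1 against 79868 CPM in knockout 2.

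Chief cell genes, which encode digestive zymogens, separated the knockout libraries from each other. The median of the 11 tested members lay 4.11 log2 units below the wild-type mean in knockout 1 and 0.28 above it in knockout 2. Pgc, the pepsinogen C gene, was at 63619 and 145530 CPM in wild type and at 2238 and 79868 CPM in knockout. Gif, the intrinsic factor gene, was at 631 and 2164 CPM against 42.5 and 1268 CPM, and Pga5 at 101 and 114 CPM against 38.6 and 231 CPM. Slc9a3, a sodium-proton exchanger gene of the list, was at 1.05 and 1.15 CPM against 13.7 and 14.7 CPM and was the only member to pass when adjusted over the list alone. The list did not pass (camera adjusted p = 0.665), but it did without knockout 2, where its mean was -3.33 (camera adjusted p = 0.0119). Surface pit cell genes did not pass either (camera adjusted p = 0.144, 9 of 14 members lower, median -0.35). Without wild type 2 their mean was -0.36 and they passed (camera adjusted p = 0.0142). The pit mucin Muc5ac was at 12431 and 7345 CPM in wild type and 5778 and 4872 CPM in knockout, Gkn1 at 37971 and 25708 CPM against 13851 and 12763 CPM, and Gkn2 at 34850 and 23663 CPM against 19331 and 15546 CPM. Tff1 differed by less than its error (log2 fold change -0.04 ± 0.45, SE, n = 2 per group).

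Cell cycle genes were higher in both knockout libraries. All 32 members of the proliferation list were higher without overlap between the genotypes, 31 of them passing when adjusted over the list alone and 0 over all genes, with a median of 1.11 (camera adjusted p = 1.01e-17, adjusted p = 0.792 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, was at 9.84 ± 0.226 CPM in wild type and 33.2 ± 2.29 CPM in knockout (mean and SD, n = 2 per group), a log2 fold change of 1.75 ± 0.14 (SE). The proliferation marker Mki67 was at 74.8 ± 20.9 CPM against 138 ± 19.7 CPM (0.88 ± 0.27). The medians were 1.21 in knockout 1 and 1.08 in knockout 2. Targets of p53 rose as a list (15 of 16 members higher, 7 passing when adjusted over the list alone, median 1.05, camera adjusted p = 2.1e-05, adjusted p = 0.792 with an estimated correlation). Among them the cell cycle inhibitor gene Cdkn1a was at 300.1 and 190.3 CPM in wild type and 696 and 458 CPM in knockout, and the stress cytokine gene Gdf15 at 0.444 and 0.260 CPM against 9.28 and 4.42 CPM. The gland stem and progenitor list did not pass (camera adjusted p = 0.135, median 0.43), except without wild type 2, where its mean was 0.59 (camera adjusted p = 0.0377). Lgr5 differed by less than its error (log2 fold change -0.10 ± 0.89).

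Tuft cell genes were higher, with 12 of 12 members higher, 2 passing when adjusted over the list alone, and a median of 0.53 (camera adjusted p = 4.9e-04, adjusted p = 0.792 with an estimated correlation). The cyclooxygenase gene Ptgs1 was at 4.2 and 16.6 CPM in wild type and 72.3 and 67.3 CPM in knockout, and the tuft cell kinase Dclk1 at 20.8 and 24.5 CPM against 37.4 and 36.4 CPM. Intestinal genes rose as a list (11 of 12 members higher, 2 passing when adjusted over the list alone, median 1.64, camera adjusted p = 0.00119, adjusted p = 0.792 with an estimated correlation). The list lost its call without knockout 1, where its mean went from 1.94 to 0.90 (camera adjusted p = 0.0511), and its median was 3.02 in knockout 1 and 0.56 in knockout 2. Fcgbp, a mucus protein gene, was at 1.05 and 1.09 CPM against 273 and 48.3 CPM, the intestinal mucin Muc2 at 0.847 and 0.417 CPM against 2.33 and 3.06 CPM, and the intestinal regulator Cdx2 had 0 and 0 counts against 9 and 0. Muc5b, a further gel-forming mucin, differed by less than its error (log2 fold change 0.46 ± 0.80). Enteroendocrine genes fell as a list (12 of 14 members lower, none passing when adjusted over the list alone, median -1.34, camera adjusted p = 0.00714, adjusted p = 0.792 with an estimated correlation). The histamine-synthesising enzyme gene Hdc was at 9.48 and 18.7 CPM against 1.12 and 2.56 CPM. The mean of the list was -1.18, and the call was lost without wild type 2 (mean -0.78, camera adjusted p = 0.0530) and without knockout 1 (mean -0.70, camera adjusted p = 0.156).

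The title of the series concerns glycosylation and Golgi stress. The transcript lists fixed for them did not pass, and transcripts measure neither glycans nor the Golgi itself. The 29 tested Golgi structure and Golgi stress genes had a median of 0.01, a mean of -0.07 and a test direction of lower (camera adjusted p = 0.637), with 16 members higher and 13 lower. Golgb1, which encodes the Golgi tether giantin, was at 170 and 135 CPM in wild type and 112 and 101 CPM in knockout (log2 fold change -0.52 ± 0.19, SE, n = 2 per group, edgeR adjusted p = 0.324). Golga2, which encodes GM130, had a log2 fold change of 0.19 ± 0.16. The unfolded protein response list had 23 of 35 members higher and a median of 0.15 (camera adjusted p = 0.135), and it passed without knockout 1, where its mean was 0.20 (camera adjusted p = 0.0342). None of its members passed when adjusted over the list alone. Hspa5 was at 640 and 561 CPM against 1096 and 760 CPM (edgeR adjusted p = 0.380) and Pdia4 at 82.5 and 82.5 CPM against 185 and 160 CPM, while Ddit3 was at 10.2 and 8.80 CPM against 7.31 and 15.2 CPM. COPI and COPII trafficking genes had a median of 0.15 (26 of 32 higher, camera adjusted p = 0.0790) and passed without knockout 1, where their mean was 0.20 (camera adjusted p = 0.0391). N-glycan processing genes had a median of 0.20 (33 of 46 higher, camera adjusted p = 0.0624). They passed under upper-quartile factors (camera adjusted p = 0.0406), under library sizes without the 20 most abundant genes (camera adjusted p = 0.0473) and under the filter of 50 counts (camera adjusted p = 0.0429).

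Mucin-type O-glycosylation genes went both ways. Of 31 tested, 18 were higher and 13 lower (median 0.11, camera adjusted p = 0.446), and 3 higher and 2 lower members passed when adjusted over the list alone. The blood group transferase Abo was at 0.363 and 0.521 CPM in wild type and 16.8 and 8.59 CPM in knockout, and the initiating enzyme Galnt5 at 8.23 and 7.14 CPM against 31.2 and 25.2 CPM. The fucosyltransferase Fut4 was at 232 and 173 CPM against 53.5 and 44.0 CPM, and B4galnt3 at 86.5 and 51.6 CPM against 22.2 and 21.6 CPM. The 17 tested genes near Muc6 on chromosome 7 had a median of 0.00051, a mean of 0.04 and a test direction of lower (camera adjusted p = 0.722).

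The mitochondrial transcript and ribosomal protein lists had been fixed as measures of RNA quality, and both differed by genotype, as did the other lists called here. Mitochondrial transcripts fell as a list (13 of 13 lower, 11 passing when adjusted over the list alone, median -1.09, camera adjusted p = 1.2e-11, adjusted p = 0.792 with an estimated correlation), as did nuclear oxidative phosphorylation genes (35 of 36 lower, 0 passing when adjusted over the list alone, median -0.52, camera adjusted p = 4.2e-11, adjusted p = 0.792 with an estimated correlation). All 37 cytosolic ribosomal protein genes were higher (0 passing when adjusted over the list alone, median 0.38, camera adjusted p = 3.9e-08, adjusted p = 0.792 with an estimated correlation). Cholesterol synthesis genes rose as a list (20 of 21 higher, 0 passing when adjusted over the list alone, median 0.42, camera adjusted p = 5.6e-04, adjusted p = 0.849 with an estimated correlation), as did ERK MAPK targets (17 of 20 higher, 2 passing when adjusted over the list alone, median 0.38, camera adjusted p = 0.00714, adjusted p = 0.792 with an estimated correlation). Among the ERK targets Etv4 was at 3.75 and 3.18 CPM in wild type and 12.9 and 12.4 CPM in knockout, and the cyclin gene Ccnd1 at 55.7 and 47.9 CPM against 198 and 127 CPM. Immediate early genes, which respond to tissue handling as well as to growth factors, rose too (14 of 18 higher, 0 passing when adjusted over the list alone, median 0.57, camera adjusted p = 0.00998, adjusted p = 0.792 with an estimated correlation). Without knockout 1 these 3 lists did not pass. The mean went from 0.50 to 0.15 for cholesterol synthesis (camera adjusted p = 0.0873), from 0.64 to 0.35 for ERK targets (camera adjusted p = 0.287) and from 0.62 to 0.49 for immediate early genes (camera adjusted p = 0.0690). The medians were 0.83 in knockout 1 and 0.18 in knockout 2 for cholesterol synthesis, 0.82 and 0.17 for ERK targets and 0.66 and 0.26 for immediate early genes.

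The squamous forestomach list rose (8 of 9 tested members higher, 6 passing when adjusted over the list alone, camera adjusted p = 5.2e-04, adjusted p = 0.792 with an estimated correlation). Its median was 3.41 as computed and 3.69 with 3 members at 0 in wild type set to their bounds. Krt13 was at 0.847 and 0.260 CPM in wild type and 117 and 5.62 CPM in knockout 1 and 2, and Krt14 had 0 counts in wild type and 239 and 107 in knockout, at least 109-fold higher against a floor of 3 counts over the wild-type group. Krt5 had 29 counts in knockout 1 and 0 in the other libraries, and Trp63, Sprr3 and Krtdap had 0 in all 4. Sprr2a1 was at 1172 and 834 CPM in wild type and 909 and 737 CPM in knockout, and the list summed to 1208 and 856 CPM against 1267 and 783 CPM. The antral list did not pass (4 tested members, camera adjusted p = 0.338). In knockout 1, however, gastrin (Gast) had 218 counts against 1, 0 and 0 in wild type 1, wild type 2 and knockout 2, Onecut2 532 against 6, 8 and 1, Nkx6-3 2716 against 9, 6 and 11, and Pdx1 1316 against 7, 1 and 61. These antral genes, the low chief and parietal values and the higher of the SPEM medians occurred in the same library.

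**Figure D2:**
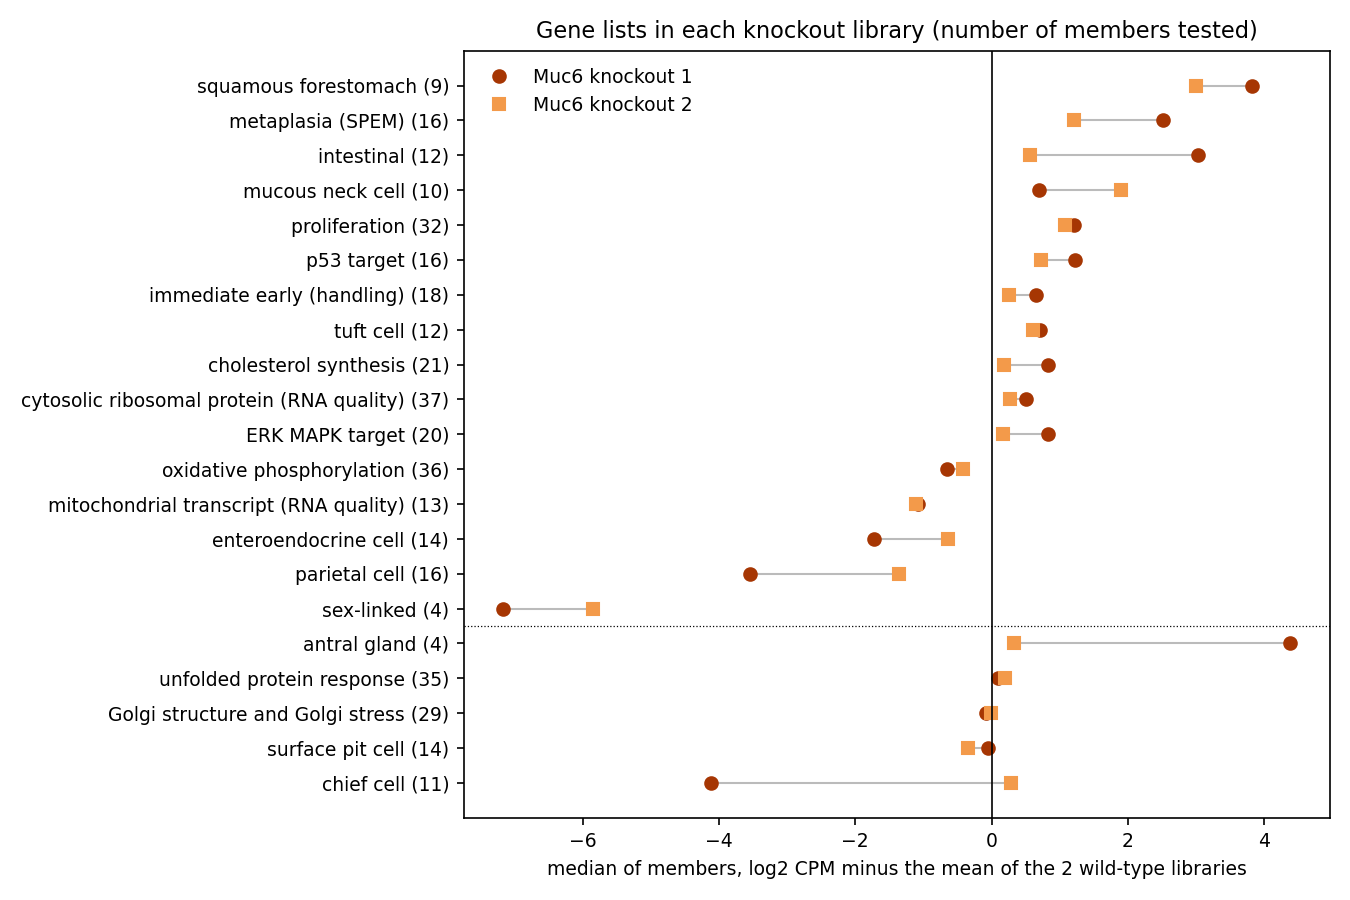
Each point is the median, over the tested members of a gene list, of log2 CPM in knockout 1 (circles) or knockout 2 (squares) minus the mean of the 2 wild-type libraries, with the number of members in brackets and the 16 lists that passed camera above the dotted line. The knockout libraries lie together for proliferation (1.21 and 1.08) and apart for chief cell genes (-4.11 and 0.28).

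No immune or stromal list passed in the fit without a block. In that fit the interferon response list had a median of -0.28 (camera adjusted p = 0.338), fibroblast and extracellular matrix 0.19 (0.753), smooth muscle 0.08 (0.801) and inflammatory cytokines and chemokines 1.21 (0.662), where the bracketed values are camera adjusted p-values. With the sample number as a block, the interferon list passed as lower (mean -0.35, camera adjusted p = 0.00528). The labels do not state that equal numbers pair the libraries. Some of these calls changed when a single library was left out. Without wild type 1 the fibroblast list had a mean of -1.26 (camera adjusted p = 0.0141) and the smooth muscle list -1.06 (0.0491), while without wild type 2 they had 1.73 (4.6e-04) and 1.47 (0.0136), and without knockout 1 the fibroblast list had 1.31 (0.0426). The interferon list had -1.33 without wild type 2 (1.1e-04) and -1.47 without knockout 1 (0.00180). The cytokine list passed without a count filter, where its mean was 0.88 (camera adjusted p = 0.0318). Among the cytokines, the alarmin gene Il33 was at 291 and 162 CPM in wild type and 63.6 and 34.6 CPM in knockout. The remaining lists that did not pass had camera adjusted p-values of 0.0778 for circadian clock genes, 0.0790 for Wnt targets, 0.111 for liver, 0.115 for exocrine pancreas, 0.135 for heat shock, 0.254 for mucins, 0.293 for endothelium, 0.398 for macrophages and dendritic cells, 0.446 for antigen presentation, 0.665 for B and plasma cells, 0.722 for adipocytes, 0.730 for neutrophils and for skeletal muscle, 0.739 for enteric neurons and glia, 0.749 for erythroid cells, 0.781 for glycolysis and 0.80 for eosinophils and mast cells.

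Among the genes with the smallest p-values, Ces2a, a carboxylesterase of a family of near copies, was at 10.5 and 10.5 CPM in wild type and 724 and 547 CPM in knockout (log2 fold change 5.92 ± 0.28, SE, n = 2 per group). The tight junction gene Cldn2 had 5 counts in wild type and 4728 in knockout, a ratio of 894 (95% interval 383 to 2755). Ambp (5.60 ± 0.33), Slc9a3 (3.69 ± 0.24), Fam89a (4.19 ± 0.31) and the coronin Coro2b (1.73 ± 0.13) were also higher on the log2 scale. Lower values were found for the morphogen Shh, made by parietal and pit cells (-2.07 ± 0.16), and for Sgk1 (-2.47 ± 0.24) and Fkbp5 (-2.99 ± 0.29). Lower values were also found for the mitochondrial subunit mt-Nd3 (-2.84 ± 0.20) and for the mitochondrial transhydrogenase Nnt (-2.20 ± 0.13). The annotation holds 2 overlapping entries for Nnt, and the other had 393 and 335 counts in wild type and 95 and 480 in knockout, so the value of Nnt is uncertain. Processed pseudogenes were among the genes with the smallest p. Vcp-rs had 0 counts in both wild-type libraries and 2159 and 2132 in knockout, at least 1352-fold higher, Rps2-ps10 a ratio of 312 (95% interval 246 to 402) and Atp6v0c-ps2 a ratio of 521 (95% interval 144 to 4303). Rpl3-ps1 had 5350 and 3569 counts in wild type and 4 and 27 in knockout. These 4 share sequence with expressed parent genes.

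By edgeR's quasi-likelihood test 0 of 14067 genes were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.104. At an unadjusted p under 0.05 there were 1297 higher and 939 lower genes, where chance gives about 703 in all, and library sizes without the 20 most abundant genes gave 1706 higher and 640 lower, a share of 72.7% higher against 58.0%. DESeq2 called 571 higher and 473 lower genes and limma voom 0 and 0. The genotypes did not overlap for 7042 genes (50.1%), against 33.3% by chance. Of the lists, 11 rose and 5 fell by camera, with 0 members of any list passing over all genes tested, while 0 passed with an estimated correlation and 0 by fry. The estimated correlation was -0.080 for tuft cells, -0.011 for mucous neck cells and 0.0041 for immediate early genes, below the preset 0.01. It was 0.953 for sex-linked genes, yet the adjusted p with an estimated correlation was 0.792 for each of these lists. Members that vary together thus cannot alone account for the lost calls. Without wild type 1 there were 14 lower lists and without knockout 2 there were 8. Leaving out knockout 2, so that knockout 1 alone stood against wild type, gave 302 higher and 442 lower genes by edgeR, and leaving out any other library gave 0 and 0. Of those 302 and 442 genes, 210 and 214 were also called by DESeq2 on all 4 libraries. Without a count filter edgeR called 5 higher genes (Vcp-rs, Ces2a, Rps2-ps10, Ambp and Cldn2) and 4 lower genes (Ddx3y, Uty, Kdm5d and Nnt).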

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

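The edgeR fit with the bias-adjusted deviance was chosen after the data were seen and gave 0 higher and 0 lower genes. The planned condition of at least 2-fold changed nothing, since no gene passed the adjusted threshold. Muc6 had a log2 fold change of -10.66 by DESeq2 (adjusted p = 6.0e-06) and of -15.85 to -9.66 when single libraries were left out, where -15.85 rests on a knockout library with 0 counts and is set by the fit, not a measured size. Genes higher numbered 5 without a count filter, 571 by DESeq2 and 0 to 302 when single libraries were left out, and genes lower 4, 473 and 0 to 442. Lists higher and lower numbered 0 and 0 both with an estimated correlation and by fry. Leaving out single libraries gave 11 to 15 lists higher and 5 to 14 lower. Where a library is left out, the lone library of its group is assumed to vary like the other group. The replicate number as a block gave 0 higher and 0 lower genes, 11 lists higher and 8 lower, among them interferon response (mean -0.35, camera adjusted p = 0.00528), and -0.18 for Pga5 and 0.091 for Lgr5. The deviations of number 1 from the genotype means correlated at 0.517 across genes, over 2 pairs that the labels do not state to be pairs. By voom Pga5 was at -0.21 and Lgr5 at 0.26, and Tff1 was at 0.0056 without the 20 most abundant genes. The Muc6 neighbour list had a mean of -0.0049 without a count filter and of -0.061 without shared members. Leaving out single libraries gave log2 ranges that cross 0: -0.39 to 0.29 for Tff1, -0.49 to 1.84 for A4gnt, -1.53 to 1.06 for Pga5, -5.12 to 0.054 for Gif, -0.86 to 1.26 for Lgr5, -0.43 to 0.63 for Ddit3 and -0.22 to 1.84 for Muc5b. List means crossed it for chief cells (-3.33 to 0.42), interferon response (-1.47 to 0.68), fibroblasts (-1.26 to 1.73), smooth muscle (-1.06 to 1.47) and Muc6 neighbours (-0.10 to 0.098). Except where fewer samples or genes entered the fit, the cause was not tested. Of 16 lists called by camera, 10 kept the call without any single library and 15 under every scaling. In the other values, named genes kept direction and side of the threshold in 370 and passed it in 35 under settings with all libraries, and in 132 and 23 with a library left out. Lists did so in 226, passed it in 5 and lost it in 34, and with a library left out in 94, 10 and 7. Depth limits the genes near 0, where 1 count in these libraries is a large part of the value.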

Other observations

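Genes chosen after their values were seen add to the description of the knockout mucosa. Pdk4, a kinase that restrains glucose oxidation, was at 107 and 97.7 CPM in wild type and 15.2 and 22.5 CPM in knockout. The estrogen receptor gene Esr1 was at 4.12 and 4.90 CPM against 0.179 and 0.413 CPM. Foxj1, the regulator of motile cilia, was at 0.363 and 0.156 CPM in wild type and 5.29 and 7.18 CPM in knockout. Trim29 and Grhl3, genes of stratified epithelia, were at 0.0403 and 0.104 CPM and at 0 and 0.104 CPM in wild type, against 46.5 and 8.09 CPM and 24.2 and 4.30 CPM in knockout 1 and 2. Within the cytokine list, which did not pass (camera adjusted p = 0.662), knockout 1 had 45 counts of Cxcl2 against 2, 7 and 1 in wild type 1, wild type 2 and knockout 2, 44 of Ccl20 against 4, 0 and 1, and 81 of Il1a against 11, 4 and 10. Of all 32 members, filtered or not, 20 were highest in knockout 1 in CPM and 11 of these at least 5 times above every other library, among them Ltf at 37.2 CPM against 0.121, 0.260 and 0.867 CPM, while others were not, with Il33 at 1418 counts against 7222, 3104 and 837 and Il18 at 90.9 CPM against 111, 87.4 and 66.5 CPM. The tally has no floor, and the 11 include Il17a, with 1 count in knockout 1 and 0 in each other library.

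Stromal, macrophage and interferon genes differed between libraries within each genotype. Replicate 1 minus replicate 2, as the median over list members on the log2 scale, was -3.28 in wild type and -2.77 in knockout for fibroblast genes, -2.56 and -2.25 for smooth muscle, -2.49 and -1.84 for endothelium and -2.86 and -1.77 for macrophages and dendritic cells. For interferon response genes it was 2.26 and 2.07. No test was run on these differences, since each rests on single libraries.

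Of the tests that follow, that of smooth trends on length and GC content was chosen before its result was seen and the others after. Chief and parietal cell genes lay far lower in knockout 1 than in knockout 2, with medians 4.30 and 2.54 log2 units lower, which a length or GC bias, or antral tissue in the sample, could produce. Removing smooth trends on transcript length and GC content left the chief cell median at -4.27 but moved genes by a median of only 0.0164, while the 20 genes nearest to each chief cell gene in length and GC content differed by medians of -0.19 to 0.50 (over the list -0.00499), which argues against that bias as the whole cause. Antral tissue in knockout 1, which could also add to its SPEM genes (median 2.52 against 1.21 in knockout 2), remained open: 4 of 6 antral list members with counts were at least 5 times above every other library there, while somatostatin (Sst) was lowest there, at 462 counts against 2194, 4167 and 3228. In knockout 2, Pdx1 had 61 counts against 7 and 1 in wild type, but Nkx6-3 11 against 9 and 6 and Gast 0 against 1 and 0. There the chief cell median was 0.28 against the wild-type mean (SD of members 1.30), where dilution by antral tissue needs the -1.36 of the parietal list. Against wild type 1 alone the chief and parietal medians were 1.01 and -1.44, and against wild type 2 alone -0.51 and -1.32. The gap against wild type 2 is smaller than that SD, so the outcome depends on the wild-type library. The test thus cannot decide whether antral tissue accounts for the lower parietal cell genes of knockout 2. Loss of the cells themselves after loss of Muc6 was not tested and stays open.

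The genotypes also differed in 27 genes that were under 0.5 CPM in both libraries of a genotype and above 4 CPM in both of the other, 21 near 0 in wild type and 6 in knockout. The 6 include Muc6 and the Y-linked Ddx3y and Eif2s3y, which follow the difference in Y-linked expression between the genotypes. Of the 26 besides Muc6, 0% lay within 20 Mb of it, which argues against DNA flanking the targeted locus. A strain variant against the reference, with reads shared between a gene and its processed pseudogenes, may account for part of them: 22.2% were processed pseudogenes against 1.49% of all genes tested (Fisher's exact test, two-sided, p = 2.3e-06). All genes tested were not matched on expression to these genes, which were picked for values near 0, so the p-value cannot decide this. For 4 of 4 parent and copy pairs examined, of which only the copies of Vcp and Atp6v0c are among the 27 genes, the knockout to wild-type ratio of the sum was closer to 1 on the log2 scale than that of the parent, at 1.06 against 0.780 for Vcp, 1.36 against 0.663 for Rps2, 1.24 against 2.09 for Rpl3 and 0.930 against 0.825 for Atp6v0c. The pairs were picked because their copies had among the smallest p here, so they give no separate support. The strains of the animals are not given in the sources used here.

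Differences between the genotypes in genes other than Muc6 could also come in part from the sex of the animals. There were 0 genotypes whose 2 libraries differed by more than 3 log2 units in Y-linked expression, with sums of 136 and 121 CPM in wild type and 1.43 and 2.44 CPM in knockout, so for these genes sex and genotype cannot be told apart in these libraries.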
